A study of Mus musculus with 9 samples.

How the data were processed

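Poly(A) RNA of mouse cardiac tissue was sequenced in 9 libraries, 3 each from young mice given vehicle, aged mice given vehicle and aged mice given MLN4924. Per the labels' protocols, poly(A) RNA was purified on oligo(dT) beads, fragmented, copied with random hexamer primers and amplified by PCR, and the products were circularised for sequencing on DNA nanoballs. The labels name no step that keeps the strand, so overlapping and antisense genes are uncertain. The deposited table holds an estimated count per gene and library, with NCBI Gene numbers and symbols, per the file headers and values. HISAT2 2.2.1, DESeq2 1.42.1 and the build GRCm38 are listed with no role or order, per the submitters' processing notes, and the program that estimated the counts is not given in the sources used here.

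Of the values, 5.54% were not whole, and these were rounded to whole numbers before testing. The table holds 17605 genes, of which 17557 were matched by NCBI Gene number to a reference table of the same build for names and coordinates and 48 were not. A count of 3 corresponded to 0.188 to 0.253 CPM relative to the unscaled library totals, while the other CPM values are relative to the TMM-scaled totals. PCR copies are not independent molecules, so such floors cover counting error only. No replicate pair of a group agreed within sampling noise, and all 9 libraries were used.

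Groups were taken from the labels. With edgeR 4.0.16 in R 4.3.3, genes were filtered with filterByExpr, scaled with TMM and fitted over all 9 libraries with a coefficient per group and robust dispersion. Each of the 3 comparisons was tested with the quasi-likelihood test and Benjamini-Hochberg adjustment over the 13313 genes tested, at a threshold of 0.05. Of 53 gene lists written, 50 had at least 3 tested members. Each was tested with camera from limma 3.58.1 (preset correlation 0.01), with adjustment over the 50 lists, and again with an estimated correlation and with fry, and members were also adjusted over the list alone. The design, the lists, the rule for named genes and the settings to be varied were fixed before the data were examined. Log2 CPM values for list levels used a prior count of 2.

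The rule for named genes takes, for aged against young vehicle and MLN4924 against aged vehicle, the 8 largest rises and 8 largest falls past the threshold among genes with a mean log2 CPM of at least 1 whose groups do not overlap, leaving out predicted genes, clones and pseudogenes. For MLN4924 against young vehicle it takes 5 of each. Where fewer than 8 pass, it takes the 8 with the smallest unadjusted p. It adds up to 4 members of each list described, by the smallest p, and 19 tested genes of neddylation, mitophagy, remodelling and senescence. Results of some genes that the rule or a setting would name are not reported here. The planned naming of genes that moved back toward young was not possible, since no gene passed with age.

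The steps were tested on simulated counts made from the mean levels and dispersions over all 9 libraries, with 200 of 13313 genes changed. For the simulated aged against young comparison, edgeR recovered 8, 23, 47 and 47 of 50 genes at folds of 1.5, 2, 4 and 8 with 4 false calls (3.1%), DESeq2 1.42.0 recovered 12, 30, 50 and 49 with 21 (13%), and limma-voom 7, 22, 47 and 47 with 2 (1.6%). Camera called the 1 changed list and 0 of the others. The simulated genes were drawn independently, so camera's false calls for lists whose members vary together were not tested.

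The settings varied from the start were RLE and upper-quartile scaling, DESeq2, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block, no robust estimation, and each library left out in turn. Added after seeing the data were an atrial covariate, a covariate for Y-linked transcripts, the 6 libraries low in atrial transcripts, and a lowess correction (span 0.3) for transcript length, which 97.9% of tested genes had. The mean log2 levels of 5 lists were also fitted per library with the atrial covariate, with 95% intervals from the residual spread between libraries (5 degrees of freedom). Length-matched lists were 10000 random draws per list from the 100 nearest genes in length and expression. Opposite fold changes were set beside 100 simulations of unchanged groups that share the aged vehicle libraries, and DESeq2's calls beside 20.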

Results

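Poly(A) RNA from mouse cardiac tissue was sequenced in 9 libraries, 3 each from young mice given vehicle, aged mice given vehicle and aged mice given MLN4924, a small-molecule inhibitor of the NEDD8-activating enzyme. That enzyme starts neddylation, the attachment of the ubiquitin-like protein NEDD8 to cullins and other targets. The total counts were 11856097, 13930138 and 15353071 in young vehicle 1 to 3, 15951139, 12586545 and 15863548 in aged vehicle 1 to 3, and 14178889, 13406149 and 13657756 in aged MLN4924 1 to 3. Of 17605 genes in the table, 13313 had enough counts to be tested. Unless stated otherwise, each ± after a CPM (count scaled to the effective library size) is the SD over 3 libraries. Each ± after a log2 fold change is its standard error. The labels do not state the age in months, the dose, the sex or which part of the heart was taken. They also do not state that each library came from a separate mouse. Y-linked genes averaged 34.1 CPM or more in some libraries of each group and 0.457 CPM or less in the others. This argues against the same mouse behind all libraries of a group, and each group appears to mix the sexes. Libraries alike in Y-linked transcripts could still share a mouse. The p-values therefore measure the spread between these libraries, which may be partly technical.

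The libraries differed within groups in transcripts of atrial cardiomyocytes. Myl7, the atrial myosin light chain, stood at 1690 CPM in young vehicle 3, 3830 in aged vehicle 1 and 2320 in aged vehicle 3. It was at 157 and 145 CPM in young vehicle 1 and 2, at 2.03 in aged vehicle 2, and at 1.91, 1.52 and 0.781 in the treated libraries. Sln, the atrial inhibitor of the calcium pump, and Nppa, which encodes atrial natriuretic peptide, were distributed in the same way, with Nppa between 114 CPM (aged MLN4924 3) and 15600 CPM (aged vehicle 1). The first principal component, with 48.8% of the variance, had positive scores in young vehicle 3, aged vehicle 1 and aged vehicle 3 and negative scores in the other 6 libraries. Adipocyte markers were highest in aged vehicle 1 and aged vehicle 3, at 3.61 and 2.09 on the log2 scale relative to the mean of the 9 libraries, and haemoglobin transcripts took 14.8% of the counts of aged vehicle 3 against 0.396% to 1.73% elsewhere. Ddx3y, a Y-linked helicase gene named after its values were seen, was at 0 to 0.693 CPM in young vehicle 3, aged vehicle 3, aged MLN4924 1 and aged MLN4924 3 and at 57.3 to 84.3 CPM in the other 5 libraries. Further fits, all chosen after these values were seen, used the atrial list's mean level or the presence of Y-linked transcripts as a covariate or removed a trend with transcript length. Another kept only the 6 libraries low in atrial transcripts, where aged vehicle is 1 library that is assumed to vary like the other groups. The atrial list's mean level was still uneven among these 6, at 0.551 and -0.406 in young vehicle 1 and 2. It was at -3.04 in aged vehicle 2 and at -2.66, -2.71 and -3.03 in the treated libraries. Comparisons with young vehicle over the 6 libraries thus remain mixed with a difference in atrial transcripts.

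**Figure D1:**
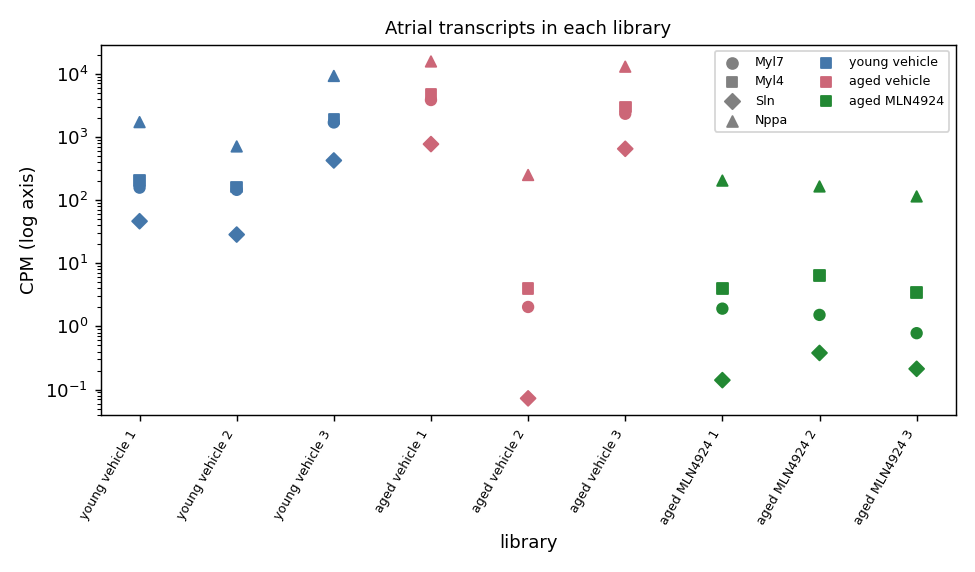
CPM (log axis) of Myl7, Myl4, Sln and Nppa in each of the 9 libraries, coloured by group; each point is 1 library. Young vehicle 3, aged vehicle 1 and aged vehicle 3 hold the highest values of all 4 genes, with Nppa at 9200, 15600 and 12900 CPM.

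The comparison of aged with young vehicle mice asks how cardiac expression differs with age. Transcripts of nuclear-encoded mitochondrial and of translation machinery were lower in aged vehicle. All 36 genes of complex I, the entry point of electrons into the respiratory chain, had lower means, with a median log2 fold change of -1.09. All 42 genes of complexes II to V were lower, with a median of -1.04. Cytosolic ribosomal proteins had a median of -0.82 (67 of 68 lower), mitochondrial ribosomal proteins -0.76 (68 of 69 lower) and proteasome subunits -0.55 (31 of 31 lower). Camera, with its preset correlation, called all 5 lists (adjusted p = 3.5e-28, 3.5e-28, 3.2e-30, 1.1e-29 and 1.4e-15), and each had an adjusted p = 0.89 with an estimated correlation. Over all genes, 0 members of these lists passed edgeR's quasi-likelihood test, while adjusted over the list alone 35, 41, 67, 61 and 26 members passed, all of them lower.

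Ndufv1, a core complex I subunit, averaged 1350 ± 211 CPM in young vehicle and 780 ± 14 in aged vehicle, a log2 fold change of -0.79 ± 0.15. Ndufa1 was at 439 ± 216 and 164 ± 13.1 CPM, and Cox7c, of cytochrome c oxidase, at 1280 ± 411 and 599 ± 16.7. Mrps28, of the small mitochondrial ribosomal subunit, had a log2 fold change of -1.03 ± 0.18, Rps2 one of -0.85 ± 0.18, and Psmb5, a catalytic subunit of the proteasome, was at 172 ± 47.8 and 85.9 ± 7.37 CPM. The SDs in young vehicle were wide because the young libraries differed: the complex I list was at 1.01, 0.44 and -0.08 on the relative log2 scale in young vehicle 1 to 3, against -0.69, -0.35 and -0.63 in aged vehicle 1 to 3. Without young vehicle 1 the median of the cytosolic ribosomal list was -0.50, and after a correction for transcript length it was -0.52. The fold changes also followed transcript length. Across genes, which are not independent replicates, Spearman's rho between length and the log2 fold change was 0.38, and the 5 lists have median transcript lengths of 645 to 1239 bases. Per library, rho with length was -0.41, -0.27 and 0.08 in young vehicle and 0.3, 0.3 and 0.24 in aged vehicle.

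**Figure D2:**
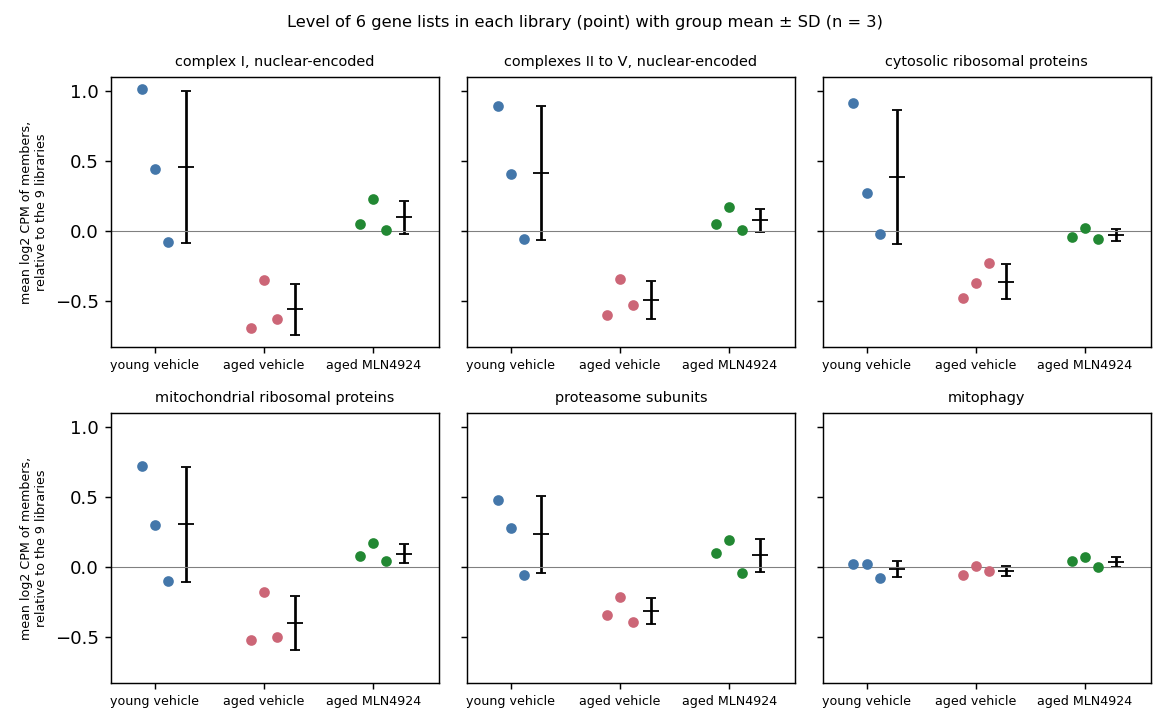
Mean log2 CPM of the members of 6 gene lists, relative to the mean of the 9 libraries; points are libraries and the black marks give the group mean ± SD (n = 3). Complex I is lowest in the aged vehicle libraries (-0.69, -0.35 and -0.63), and the mitophagy list lies between -0.08 and 0.07 in all 9 libraries.

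**Figure D3:**
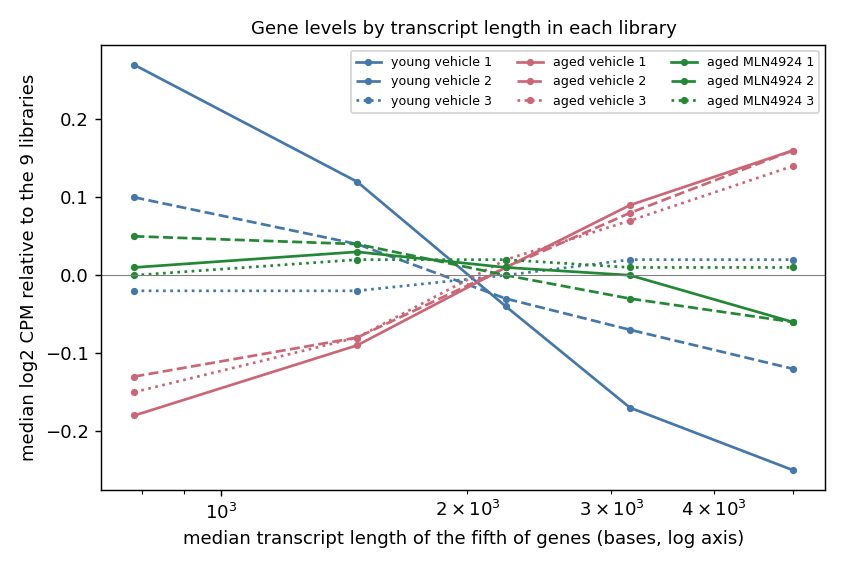
Median log2 CPM, relative to the mean of the 9 libraries, in 5 bins of genes ordered by transcript length (x axis: median length of the bin in bases, log axis); each line is 1 library, coloured by group. Aged vehicle libraries lie at -0.18, -0.13 and -0.15 for the bin of shortest transcripts and at 0.16, 0.16 and 0.14 for the longest, and young vehicle 1 runs the other way, from 0.27 to -0.25.

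Camera called 5 further lists lower in aged vehicle, those of ventricular cardiomyocytes, fatty acid oxidation, the TCA cycle, the mitochondrial unfolded protein response and glycolysis. With an estimated correlation the adjusted p was 0.89 for each of them. Ventricular cardiomyocyte genes had a median log2 fold change of -0.70, with Myl2, the ventricular myosin light chain, at 21800 ± 8930 CPM in young and 8300 ± 4050 in aged vehicle, and Tnni3, cardiac troponin I, at 13800 ± 5070 and 6310 ± 474. Within each vehicle group Myl2 was lower in the libraries with high atrial transcripts. It was at 13100 CPM in young vehicle 3 against 31000 and 21400 in young vehicle 1 and 2, and at 5390 and 6600 in aged vehicle 1 and 3 against 12900 in aged vehicle 2. Fatty acid oxidation had a median of -0.38, the TCA cycle -0.21, the mitochondrial unfolded protein response -0.29 and glycolysis -0.32 (adjusted p by camera 1.4e-05, 0.0031, 0.0047 and 0.012, after 2.2e-06 for the ventricular list). Adjusted over the list alone, 10 of 18 ventricular, 11 of 31 fatty acid, 8 of 19 TCA cycle, 5 of 13 unfolded protein response and 4 of 21 glycolysis genes passed edgeR's test, all lower. Examples are Etfb, an electron transfer flavoprotein subunit (log2 fold change -1.23 ± 0.23), Mdh2 (-0.69 ± 0.18), Clpp, a mitochondrial protease subunit (-1.06 ± 0.23), and Eno3, muscle enolase (-0.88 ± 0.22). The complement list was the only list called higher of the 50 tested (median 0.59, adjusted p = 0.015 by camera, 0.89 with an estimated correlation), with 3 of 18 members passing when adjusted over the list alone: C4b (1.58 ± 0.40), C1s1 (0.80 ± 0.22) and C3 (1.13 ± 0.32). The complement list was at 0.72 and 0.67 on the relative log2 scale in aged vehicle 1 and 3, which also held the most atrial and adipocyte transcripts, and at -0.18 in aged vehicle 2. Its adjusted p by camera was 0.067 without young vehicle 2, 0.099 without young vehicle 3, 0.099 without aged vehicle 3 and 0.77 over the 6 libraries low in atrial transcripts; that of glycolysis was 0.28 after a correction for transcript length and 0.11 over the 6 libraries. Camera with its preset correlation still called the complement list higher with the atrial covariate (adjusted p = 0.011) and after the length correction (0.0018). The complement median was 0.36 without aged vehicle 3, 0.8 without young vehicle 3 and 0.11 over the 6 libraries. The TCA cycle median was -0.13 and -0.34 without young vehicle 1 and 3 and -0.12 without aged vehicle 3.

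No single gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in this comparison: 0 of 13313, with 3837 at an unadjusted p under 0.05 (1752 higher, 2085 lower, 666 expected by chance), against 2142 genes (626 higher, 1516 lower) by DESeq2 and 0 by limma-voom. The smallest adjusted p was 0.054, shared by 410 genes. Among genes that met the rule for naming, the 8 with the smallest p were all higher in aged vehicle. Foxo3, a transcription factor of stress resistance and atrophy (NCBI Gene 56484, GRCm38 chromosome 10, 42181845 to 42276695), was at 57.7, 58.8 and 74.1 CPM in young and 117, 113 and 121 in aged vehicle, a log2 fold change of 0.88 ± 0.12. Ric3, a chaperone of acetylcholine receptors (Gene 320360, chromosome 7, 109034268 to 109083432), was at 2.14 ± 0.408 and 8.01 ± 1.85 CPM (1.91 ± 0.24). Among them were 2 acyl-CoA synthetase genes: Acsm5 (Gene 272428, chromosome 7, 119526131 to 119543360) had a log2 fold change of 1.55 ± 0.21 and Acsl6 (Gene 216739, chromosome 11, 54303805 to 54364756) one of 1.28 ± 0.18. Ppp1r3a, a glycogen-targeting subunit of protein phosphatase (Gene 140491, chromosome 6, 14713822 to 14755274), was at 78.5 ± 7.43 and 132 ± 7.86 CPM (0.75 ± 0.11). The cadherin gene Cdh22 (Gene 104010, chromosome 2, 165111501 to 165234924; 2.21 ± 0.30) and the lectin gene Cd209f (Gene 69142, chromosome 8, 4102784 to 4105838; 2.80 ± 0.40) complete the group with Csprs. Csprs averaged 0.0717 ± 0.0773 CPM in young, 2.47 ± 0.82 in aged vehicle and 3.23 ± 1.3 in treated libraries; it belongs to a repeated gene family whose reads the counting could split, so its values are uncertain.

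The count of 0 depended on single libraries and settings. It became 2693 without young vehicle 3, 1501 without aged vehicle 2, 1 without aged vehicle 1 (Prkcq) and 2 without aged MLN4924 2 (Acsm5 and Fkbp5, the latter named after its value was seen). It was 403 (123 higher, 280 lower) with upper-quartile scaling, 654 without a filter, 1946 with the atrial score as a covariate, 1207 with the presence of Y-linked transcripts as a covariate and 22 over the 6 libraries low in atrial transcripts. The number of lists called was 17 without young vehicle 1 and 18 without aged vehicle 2, against 11.

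The comparison of aged MLN4924 with aged vehicle asks what the inhibitor changes in the aged heart. The lists that were lower with age had higher means in treated libraries. Complex I had a median log2 fold change of 0.68 (36 of 36 genes higher), complexes II to V 0.60 (42 of 42), mitochondrial ribosomal proteins 0.50 (68 of 69), proteasome subunits 0.38 (31 of 31) and cytosolic ribosomal proteins 0.34 (67 of 68). Camera's adjusted p was 6.2e-19, 1.6e-18, 9.9e-24, 8.8e-14 and 2.1e-10, and with an estimated correlation the adjusted p was 0.62 for the former 4 and 0.68 for the cytosolic ribosomal list. No member passed edgeR's test over all genes, and adjusted over the list alone 18 complex I genes and 5 proteasome genes passed, all higher, and 0 of the others. The medians with the atrial covariate were 0.34, 0.31, 0.19, 0.22 and 0.22. These fold changes also followed transcript length, with a Spearman's rho of -0.34 across genes, and random lists matched on length and expression had medians of 0.29, 0.30, 0.14, 0.19 and 0.28. The former 4 lists lay above the range that held 95% of their matched lists (upper ends 0.39, 0.39, 0.21 and 0.29). The cytosolic ribosomal median lay within that range (0.17 to 0.35), and its member with the smallest p, Rpl3, went the other way, with a log2 fold change of -0.59 ± 0.20. The matched lists draw genes independently, so their range can be too narrow for lists whose members vary together.

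Ndufv1 was at 780 ± 14 CPM in aged vehicle and 1110 ± 71.1 in treated libraries (0.50 ± 0.15), Ndufa12 at 205 ± 42 and 344 ± 31.5, and Cox7c at 599 ± 16.7 and 947 ± 46.6. Psmc5, a proteasome ATPase, had a log2 fold change of 0.50 ± 0.14 and Mrpl22 one of 0.48 ± 0.13. Camera also called the TCA cycle (median 0.26, adjusted p = 8.4e-06), glycolysis (0.24, 0.00026), fatty acid oxidation (0.27, 0.00061), the mitochondrial unfolded protein response (0.22, 0.00091), ventricular cardiomyocyte genes (0.50, 2.2e-06), cytosolic heat shock (0.35, 0.0041) and the COP9 signalosome, which removes NEDD8 from cullins (0.17, 0.032), as higher. With an estimated correlation the adjusted p was 0.62 for the TCA cycle, glycolysis, the unfolded protein response and the ventricular list and 0.65 for the other 3, and adjusted over the list alone 0 of their members passed. Idh2, mitochondrial isocitrate dehydrogenase (0.76 ± 0.20), Ldhb (0.66 ± 0.19), Eci1 (0.71 ± 0.20), Cryab (0.59 ± 0.24) and Cops6 (0.40 ± 0.15) are examples. Without aged MLN4924 2 the adjusted p by camera was 0.15 for fatty acid oxidation, 0.089 for heat shock and 0.076 for COP9, and without aged vehicle 2 it was 0.095 for COP9. The heat shock median was 0.60 without aged vehicle 2 and 0.22 without aged vehicle 3, and the glycolysis median 0.42 without aged vehicle 2. With the atrial covariate the adjusted p by camera was 0.051 for glycolysis and for the ventricular list, 0.19 for COP9 and 0.93 for heat shock. After the length correction that of COP9 was 0.41. The camera direction of heat shock turned with the atrial covariate and over the 6 libraries, where its medians were 0.01 and 0.02. With the atrial covariate the medians of the TCA cycle, glycolysis, fatty acid oxidation and the unfolded protein response were 0.14, 0.16, 0.15 and 0.11. Those of the ventricular list and COP9 were 0.22 and 0.1.

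Camera called 4 further lists higher in treated libraries: the interferon response (median 0.37, adjusted p = 2.2e-05), antigen presentation (0.25, 0.0071), neutrophil markers (1.22, 0.016) and immediate early genes (0.14, 0.016). With an estimated correlation the adjusted p was 0.65, 0.73, 0.65 and 0.65. Of their members 0 passed over all genes or adjusted over the list alone. Iigp1, an interferon-inducible GTPase, was at 33 ± 5.26 CPM in aged vehicle and 57.9 ± 14.6 in treated libraries (0.81 ± 0.20), Gbp3 had a log2 fold change of 0.74 ± 0.19, and S100a9, a neutrophil calcium-binding protein, was at 6.41 ± 2.42 and 15.5 ± 9.4 CPM. With the atrial covariate the adjusted p by camera was 0.096 for the interferon list, 0.21 for the neutrophil list and 0.19 for immediate early genes, and over the 6 libraries it was 0.59, 0.47 and 0.56. The interferon median was 0.17 without aged vehicle 1 and 0.19 without aged MLN4924 1. The neutrophil list's adjusted p was 0.075 with limma-voom, 0.21 with no filter, 0.056 without aged vehicle 2, 0.11 without aged MLN4924 1 and 0.20 without aged MLN4924 2, and that list was at 1.02 and 1.16 in aged MLN4924 1 and 2 but at -0.52 in aged MLN4924 3. Antigen presentation had 0.19 with the Y-linked covariate, 0.098 after the length correction, 0.061 without aged vehicle 1, 0.14 without aged vehicle 2 and 0.33 without aged MLN4924 1, and immediate early genes had 0.083 without aged vehicle 3, 0.065 without aged MLN4924 1 and 0.10 without aged MLN4924 2. The antigen presentation median was 0.12 and 0.50 without aged vehicle 2 and 3 and 0.07 and 0.40 without aged MLN4924 1 and 2. The neutrophil median was 0.76 without aged MLN4924 1, and that of immediate early genes 0.34 without aged MLN4924 3.

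Camera called 4 lists lower in treated libraries, those of atrial cardiomyocytes, adipocytes, Schwann cells and lipid synthesis. With an estimated correlation the adjusted p was 0.62, 0.62, 0.62 and 0.65. All 11 atrial cardiomyocyte genes had lower means (adjusted p = 1.7e-07 by camera), 10 of them passing when adjusted over the list alone, among them Myl7 at 2050 ± 1930 CPM in aged vehicle and 1.4 ± 0.571 in treated libraries and Nppa at 9590 ± 8200 and 160 ± 44.9. In aged vehicle 2 these genes were at the level of the treated libraries, and over the 6 libraries low in atrial transcripts the list's direction turned, with an adjusted p of 0.32. Adipocyte genes (0.00032, 7 of 9 adjusted over the list alone) included Adipoq, which encodes adiponectin, at 19.2 ± 24.4 and 0.26 ± 0.336 CPM. Schwann cell genes (median -0.84, 0.00013) included Mbp, a myelin protein, and cholesterol and lipid synthesis (median -0.52, 0.0054) included Scd1, a fatty acid desaturase, at 204 ± 287 and 12.8 ± 1.38 CPM; 0 members of either passed adjusted over the list alone. Over the 6 libraries the adipocyte, Schwann and lipid synthesis lists had adjusted p values of 0.67, 0.26 and 0.62 by camera, and without aged vehicle 1 that of lipid synthesis was 0.069, with a median of -0.19. The adipocyte list had 0.11 with limma-voom, 0.068 with only these groups fitted and 0.24 with the atrial covariate, and lipid synthesis 0.59 with that covariate.

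**Figure D4:**
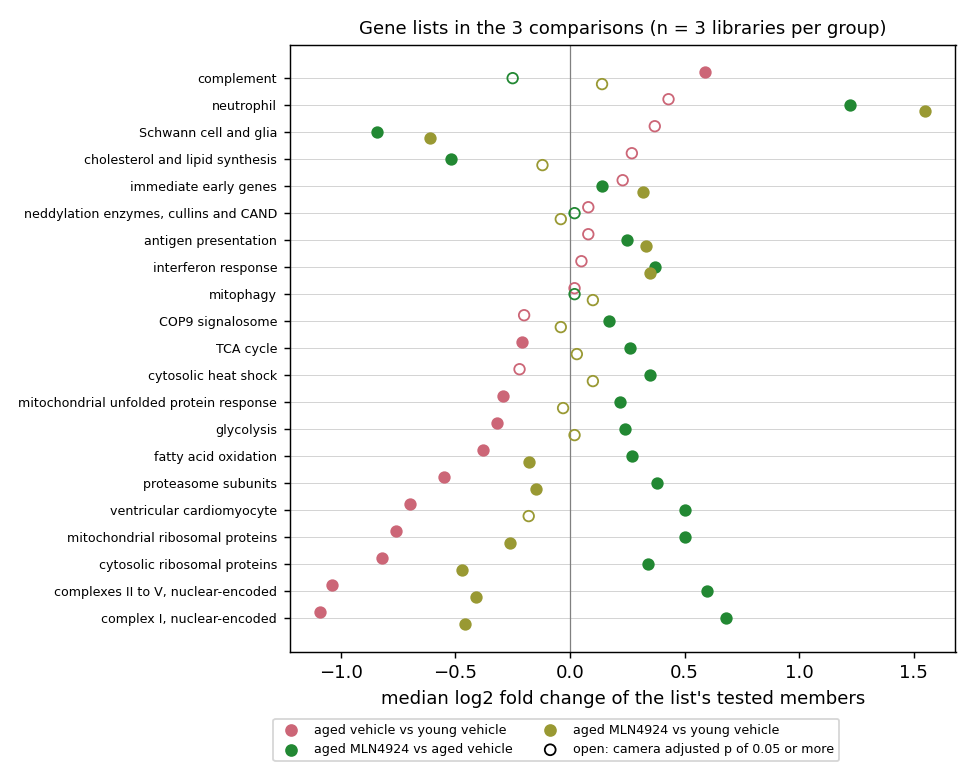
Median log2 fold change of the tested members of gene lists in the 3 comparisons (n = 3 libraries per group); filled points are lists that camera called with its preset correlation, and open points are lists it did not call; the atrial and adipocyte lists are not drawn. Complex I lies at -1.09 in aged against young vehicle, 0.68 in MLN4924 against aged vehicle and -0.46 in MLN4924 against young vehicle. With an estimated correlation 0 lists were called.

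Genes of neddylation and mitophagy, the processes that the study names, were measured as 2 lists. Of the 23 neddylation genes, 15 had higher and 8 lower means in aged than in young vehicle, with a median of 0.08, a mean of -0.05 and a camera direction of lower (adjusted p = 0.83). Adjusted over the list alone, 2 passed as higher and 4 as lower, among them Nedd8, with 139 ± 49.1 CPM in young, 69.7 ± 5.37 in aged vehicle and 101 ± 4.9 in treated libraries. Its log2 fold change was -1 ± 0.21 with age and 0.53 ± 0.21 with MLN4924. Nae1, Uba3, Cul1 and Cul3 had log2 fold changes of 0.08 ± 0.13, 0.25 ± 0.12, 0.08 ± 0.12 and 0.12 ± 0.10 with age, and of 0.03 ± 0.13, -0.07 ± 0.12, 0.02 ± 0.12 and 0.06 ± 0.10 with MLN4924. Ube2m, the NEDD8-conjugating enzyme gene, had -0.49 ± 0.19 and 0.39 ± 0.19. The list's adjusted p with MLN4924 was 0.65, and 0 of its members passed adjusted over the list alone.

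The mitophagy list of 37 genes had a median of 0.02 and a mean of -0.01 with age (camera direction lower, adjusted p = 0.83) and a median of 0.02 with MLN4924 (adjusted p = 0.24). Adjusted over the list alone, 2 members passed with age, Tomm7 (-0.99 ± 0.19) and Map1lc3a (-0.84 ± 0.20), and 0 with MLN4924. Sqstm1, the autophagy receptor p62, was at 550 ± 50.5 CPM in young, 454 ± 26.4 in aged vehicle and 588 ± 50.5 in treated libraries, with log2 fold changes of -0.28 ± 0.13 and 0.37 ± 0.13. Pink1 had -0.29 ± 0.14 and 0.23 ± 0.14, Bnip3 -0.15 ± 0.18 and 0.28 ± 0.18, and Map1lc3b -0.18 ± 0.12 and 0.14 ± 0.12. Of genes of remodelling and senescence, Nppb had 0.06 ± 0.31 and -0.15 ± 0.31, Myh6 -0.39 ± 0.17 and 0.20 ± 0.17, Myh7 0.01 ± 0.52 and 0.23 ± 0.52, Col1a1 -0.80 ± 0.29 and 0.11 ± 0.29, Col3a1 -0.96 ± 0.28 and 0.17 ± 0.28, Cdkn1a 0.27 ± 0.30 and 0.40 ± 0.30, and Ppargc1a 0.11 ± 0.20 and 0.09 ± 0.20. None of these passed edgeR's test over all genes in either comparison. Without young vehicle 3 the log2 fold changes with age were -0.36 for Col1a1 and -0.58 for Col3a1.

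In MLN4924 against aged vehicle 0 of 13313 genes passed edgeR's quasi-likelihood test, with 2342 at an unadjusted p under 0.05 (1110 higher, 1232 lower, 666 expected by chance), against 187 (49 higher, 138 lower) by DESeq2 and 0 by limma-voom. The number at an unadjusted p under 0.05 was 998, 4039 and 1221 without aged vehicle 1, 2 and 3, and 1511 and 1261 without aged MLN4924 1 and 2. With the atrial covariate it was 591 (smallest adjusted p 0.92 by edgeR), over the 6 libraries 972, and with the Y-linked covariate 3579 (smallest adjusted p 0.11). The smallest adjusted p was 0.26, shared by 1421 genes. Chd6, a chromatin helicase gene (Gene 71389, chromosome 2, 160946978 to 161109086), had the smallest p among genes that met the rule for naming. It was at 173, 99.5 and 152 CPM in aged vehicle and 57.7, 74.8 and 64.4 in treated libraries (log2 fold change -1.11 ± 0.20). Irx2, a homeobox gene (Gene 16372, chromosome 13, 72624430 to 72634196), was at 1.21 ± 0.819 and 8.48 ± 4.56 CPM (2.83 ± 0.56). Ash1l, a histone methyltransferase gene (Gene 192195, chromosome 3, 88950414 to 89079375; -0.60 ± 0.12), Trim2, a ubiquitin ligase gene (Gene 80890, chromosome 3, 84160439 to 84308352; -0.79 ± 0.16), and Pak6, a kinase gene (Gene 214230, chromosome 2, 118663045 to 118698020; -0.75 ± 0.15), had lower means. So did Nt5c1a, a nucleotidase gene (Gene 230718, chromosome 4, 123201230 to 123225339; -1.96 ± 0.40), and Tmtc1 (Gene 387314, chromosome 6, 148232430 to 148444770; -0.95 ± 0.20), while Shb, an adaptor gene (Gene 230126, chromosome 4, 45423276 to 45530828), had 0.66 ± 0.13. The count of 0 became 842 (296 higher, 546 lower) without aged vehicle 2 and 1 without aged MLN4924 2, which was Fkbp5 (-2.05), a gene outside the rule and named after its value was seen. It was 0 over the 6 libraries low in atrial transcripts.

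The design also sets treated aged mice against young mice. Cytosolic ribosomal proteins had a median log2 fold change of -0.47 (68 of 68 lower), complex I -0.46 (35 of 36), complexes II to V -0.41 (41 of 42) and mitochondrial ribosomal proteins -0.26 (65 of 69), with camera adjusted p values of 6.3e-24, 7.9e-10, 4.4e-10 and 3.5e-07 and, with an estimated correlation, adjusted p values of 0.60, 0.63, 0.63 and 0.67. Adjusted over the list alone 0 members of these lists passed. Without young vehicle 1 the medians were -0.17, -0.11, -0.13 and -0.04, and the mitochondrial ribosomal list had an adjusted p of 0.69 by camera. Without young vehicle 3 complex I had a median of -0.70 and the mitochondrial ribosomal list -0.47. The medians of complex I, complexes II to V and the mitochondrial ribosomal list were -0.71, -0.63 and -0.52 with the atrial covariate. They were -0.28, -0.27 and -0.12 with the Y-linked covariate. Smooth muscle and pericyte genes had a median of -0.15 (adjusted p = 0.00029 by camera, 0.60 with an estimated correlation), and 4 of 13 passed as lower when adjusted over the list alone. Its median was -0.03 and -0.32 without young vehicle 2 and 3, 0.03 with the Y-linked covariate and -0.64 with the atrial covariate. Acta2, smooth muscle actin (Gene 11475, chromosome 19, 34240336 to 34255585), was at 199 ± 22.5 CPM in young, 145 ± 11.2 in aged vehicle and 101 ± 16.8 in treated libraries (-0.98 ± 0.15).

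Interferon response (median 0.35, adjusted p = 1.6e-06), immediate early genes (0.32, 2e-05), antigen presentation (0.33, 0.00038) and neutrophil markers (1.55, 2e-05, with 4 of 7 passing adjusted over the list alone) were called higher by camera in treated than in young libraries. With an estimated correlation the adjusted p was 0.63, 0.60, 0.63 and 0.60. With the atrial covariate the adjusted p by camera was 0.33 for the interferon response, 0.081 for immediate early genes and 0.051 for neutrophil markers. Targets of NRF2, the regulator of antioxidant genes, had a median of 0.19 (adjusted p = 0.0020 by camera, 0.10 without young vehicle 3, 0.14 over the 6 libraries, and 0.60 with an estimated correlation). The NRF2 median was 0.12 without young vehicle 3. Without aged MLN4924 1 the interferon median was 0.18 and that of antigen presentation 0.08 (adjusted p 0.18 by camera), and the latter was 0.19 without young vehicle 2. Osgin1 was the NRF2 target that passed adjusted over the list alone, at 5.82 ± 0.779 CPM in young, 9.41 ± 1.06 in aged vehicle and 11.3 ± 0.685 in treated libraries (0.96 ± 0.16). The atrial list was lower (adjusted p = 2.3e-08 by camera, 0.60 with an estimated correlation), 7 of 11 genes passing adjusted over the list alone, and it was lower over the 6 libraries too (6.6e-68 by camera). Its median was -5.05, and -2.92 without young vehicle 3. The other 14 called lists had adjusted p values from 0.0011 (adipocyte) to 0.046 (endothelial) by camera, and from 0.60 to 0.72 with an estimated correlation. Among them mitochondrial biogenesis and the circadian clock kept the call in 3 of the 9 fits with a library left out, and senescence factors in 2. The median of 11 of these 14 lists moved by over 1.5 times without 1 library, and that of proliferation turned from 0.25 to -0.03 without aged MLN4924 1. In all, 25 lists were called, 10 higher and 15 lower, against 16 without young vehicle 3 and 15 with the atrial covariate.

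For single genes, 0 passed edgeR's quasi-likelihood test in treated against young libraries, with 946 at an unadjusted p under 0.05 (469 higher, 477 lower, 666 expected by chance), against 44 (30 higher, 14 lower) by DESeq2 and 0 by limma-voom. The number at an unadjusted p under 0.05 was 586 and 1910 without young vehicle 1 and 3, and 574 and 603 without aged MLN4924 2 and 3. It was 1735 with the atrial covariate and 2418 over the 6 libraries. The smallest adjusted p was 0.13, for 7 genes. Prkcq, a protein kinase C gene (Gene 18761, chromosome 2, 11171905 to 11301226), was at 5.48 ± 0.414 CPM in young, 15.8 ± 5.75 in aged vehicle and 19.9 ± 3.06 in treated libraries (1.86 ± 0.27). Ano5, a muscle anoctamin gene (Gene 233246, chromosome 7, 51510007 to 51598707; 3.29 ± 0.50), the amylase gene Amy1 (Gene 11722, chromosome 3, 113555952 to 113577750; 1.40 ± 0.21), which has near-identical paralogs and is uncertain, and Cds1, of phospholipid synthesis (Gene 74596, chromosome 5, 101765093 to 101823858; 1.67 ± 0.25), shared this p with Acta2, Csprs and LOC101055758. LOC101055758, another gene of a repeated family with uncertain counts, was at 0.602 ± 0.255, 2.96 ± 1.14 and 4.75 ± 1.16 CPM. Adamtsl2, a matrix glycoprotein gene (Gene 77794, chromosome 2, 27079336 to 27108981), followed at an adjusted p of 0.20 (-1.37 ± 0.22). The count was 1 without aged vehicle 1 (Prkcq), 5 when only these groups entered the fit, 19 over the 6 libraries low in atrial transcripts and 3 with the Y-linked covariate (Amy1, Acta2 and Pde11a, the last named after its value was seen).

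Whether expression in treated aged mice lies closer to that of young mice was examined from the fold changes of both aged comparisons. No gene was called with age by edgeR, so the planned share of called genes with an opposite sign has no value. Among the 2142 genes that DESeq2 called with age, 2105 (98.3%) had the opposite sign with MLN4924. In 20 simulations in which MLN4924 does nothing but the aged vehicle libraries are shared, that share was 63.8% to 67.8%. Among genes at an unadjusted p under 0.05 by edgeR, 615 were higher with age and lower with MLN4924 and 898 were lower with age and higher with MLN4924, and 2 and 1 had the same direction in both. Independent lists of these sizes would share 162 and 174, and simulations in which MLN4924 does nothing but the aged vehicle libraries are shared gave means of 118 and 106 and highest values of 145 and 124. The simulated lists were not matched in size to the observed ones, so these counts also reflect how many genes reached that p with MLN4924. The simulations draw genes independently and leave out shifts that many genes share within a library, so the distance from the simulated values can be overstated. Part or all of the excess may come from the shared aged vehicle libraries, which are too few to be split.

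Over all genes, the log2 fold changes had a correlation of -0.64 in the edgeR fit and of -0.66 from mean log2 CPM. In 100 simulations the shared libraries gave correlations of -0.33 to -0.24 without an effect of MLN4924 and of -0.53 to -0.44 without an effect of age or MLN4924. The covariance from mean log2 CPM was -0.176, against simulated means of -0.0612 (lowest -0.0773) and -0.0589 (lowest -0.067). The simulations draw genes independently and so understate the spread. The observed spread between aged vehicle libraries alone gives a covariance of -0.0952, which leaves -0.0808. Without aged vehicle 1 and without aged vehicle 3 that remainder turned positive (0.0688 and 0.045), and without aged vehicle 2 it was -0.356. Without young vehicle 3 it was -0.15, and without young vehicle 1 and 2 it was -0.0414 and -0.0516.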

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

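The fits with the atrial covariate, the Y-linked covariate, the length correction and the 6 libraries low in atrial transcripts were chosen after the data were seen. By edgeR 0 genes passed in each comparison (3837, 2342 and 946 at an unadjusted p under 0.05), as with RLE scaling, the stricter filter, no robust estimation, the length correction, limma-voom and the replicate block (0, 0 and 0). In aged against young vehicle the count was 403 with upper-quartile scaling, 2142 by DESeq2, 654 with no filter, 1946 with the atrial covariate, 22 over the 6 libraries and 1207 with the Y-linked covariate. In MLN4924 against aged vehicle it was 187 by DESeq2, and in MLN4924 against young vehicle 44 by DESeq2, 5 with only those groups fitted, 19 over the 6 libraries and 3 with the Y-linked covariate. Leaving out each library in turn gave 0 to 2693 genes (highest without young vehicle 3; 1501 without aged vehicle 2, 2 without aged MLN4924 2, 1 without aged vehicle 1), 0 to 842 (without aged vehicle 2; 1 without aged MLN4924 2) and 0 to 1 (without aged vehicle 1). The cause was not tested.

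Camera called 11, 20 and 25 of 50 lists. With an estimated correlation it called 0, 0 and 0, and fry, tested for a common direction, called 0, 0 and 0. Fry's mixed test, which lets members move either way, had adjusted p values under 0.05 with age for many lists of unlike processes. Examples are complex I (0.034), mitophagy (0.023), lysosome (0.023), endoplasmic reticulum stress (0.022), calcium handling (0.022) and p53 targets (0.023). The result was thus not particular to mitophagy. In MLN4924 against young vehicle the mixed test had 0.0038 for NRF2 targets and 0.016 for smooth muscle and pericyte genes. In MLN4924 against aged vehicle its adjusted p was 0.13 or more. Leaving out each library gave 10 to 18 lists (17 without young vehicle 1, 18 without aged vehicle 2), 16 to 23, and 16 to 24 (16 without young vehicle 3), and the atrial covariate gave 15 in MLN4924 against young vehicle. The lists of complex I, complexes II to V and cytosolic ribosomal proteins kept direction and call in all 3 comparisons and 22 settings of camera with its preset correlation. With the atrial covariate the direction turned for heat shock in MLN4924 against aged vehicle (adjusted p by camera 0.93) and, in MLN4924 against young vehicle, for proliferation (0.77), fibroblast (0.78), B cell (0.80) and adipocyte genes (0.87). Over the 6 libraries it turned for heat shock (0.58) and atrial genes (0.32) in MLN4924 against aged vehicle, and Mybphl, an atrial gene, had a fitted log2 fold change of -6.01 with age, which depends on the prior count since aged vehicle 2 was at 0.29 CPM. The correlation of the age and MLN4924 fold changes by edgeR was -0.64, from -0.77 (without aged vehicle 2) to -0.57 with a library left out, and -0.76 without young vehicle 3. It was -0.38 with the atrial covariate and -0.7 over the 6 libraries, where aged vehicle is 1 library. The simulations apply to mean log2 CPM, where the observed correlation was -0.66, and -0.45 with the atrial score removed. Without any effect they gave -0.53 to -0.44, and -0.47 to -0.40 with the atrial score removed.

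Replicate numbers did not pair the libraries: 4 of 9 same-number pairs had r over 0.1 (-0.3 to 0.51), and 3 libraries correlated best with their own number. The replicate block called 12, 22 and 25 lists. None of 648 values of named genes passed by edgeR (0 also by limma-voom), and those that passed in the same direction elsewhere were 175 of 630 by DESeq2, 41 with upper-quartile scaling, 53 with no filter, 115 with the atrial covariate, 85 with the Y-linked covariate, 3 of 629 with only the groups compared, 11 of 640 over the 6 libraries and 0 to 155 with a library left out. The planned pseudocount alternatives were not run because the file holds counts. In simulated data of this depth and size, edgeR recovered 23 of 50 genes at a fold of 2 in aged against young vehicle.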

Other observations

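The tests of a fetal gene program, of MLN4924 treatment, of atrial tissue behind the short-transcript lists and of length behind the whole covariance were chosen after the result was seen, and the bounds for MLN4924 treatment and, for opposite fold changes, for the excess and atrial tissue were changed after first results. Markers of macrophages and genes of the glucocorticoid response and the circadian clock were not called by camera in aged against young vehicle (adjusted p = 0.067, 0.15 and 0.15, and 0.95, 0.95 and 0.89 with an estimated correlation), with medians of 0.37, 0.27 and 0.29. Adjusted over the list alone, 1 of 20 macrophage, 4 of 17 glucocorticoid and 2 of 18 clock genes passed edgeR's test. Cd163, a scavenger receptor of resident macrophages, was at 12.4 ± 1.96 CPM in young, 26.6 ± 6.88 in aged vehicle and 12.6 ± 3.6 in treated libraries (SD, n = 3). Zbtb16, a glucocorticoid-induced transcription factor gene, was at 43 ± 18.4, 146 ± 22.2 and 107 ± 48.5 CPM, and Per2, a clock repressor gene, at 16.2 ± 3.74, 41.2 ± 9.6 and 31.1 ± 8.76. Dbp, a clock output gene, went the other way, at 191 ± 24.8, 116 ± 30.3 and 157 ± 12.8 CPM.

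Atrial transcripts were high in young vehicle 3, aged vehicle 1 and aged vehicle 3, with a median log2 difference of 6.03 from the other 6 libraries over the atrial list. A fetal program of a stressed ventricle is argued against, since that list without Nppa had a median difference of -0.42 (3 of 13 genes higher). MLN4924 was not given to the vehicle libraries, and for the low treated libraries it cannot be told apart from the tissue taken, since aged vehicle 2 was also low, with a median log2 difference of -0.73 from the highest treated library. Atrial tissue in some libraries may account for the pattern: 5 other atrial genes, from a list written before the test and also expressed in the other 6 libraries, had a median difference of 1.83. Among them were Pam, a secretory enzyme gene, at 2550 CPM or more in these 3 libraries and 660 or less in the others, and Kcnj3, an atrial potassium channel gene, at 218 or more and 75.1 or less. Of the ventricular genes written in the same list, Irx4 was lower in these 3 libraries (-0.91), while Hey2 went the other way (0.38).

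Lists with short transcripts were lower in aged than in young vehicle. A length trend as the whole cause is argued against, since 5 of 5 lists lay below random lists matched on length and expression, as complex I at -1.09 against a 2.5 percentile of -0.59. The random lists draw genes independently, so their range can be too narrow for lists whose members vary together between libraries. Atrial tissue as the whole cause is argued against too, since with the atrial score as a covariate the mean level of 5 of 5 lists was lower in aged vehicle, with 95% intervals below 0, as complex I at -0.98 (-1.63 to -0.32) against -1.01 without it. The matched lists were themselves lower (-0.40 for complex I), so length may account for part. Age, a difference in RNA quality between groups that length does not capture, or both may contribute, and neither was tested.

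MLN4924 fold changes were opposite to those of age, and the covariance was 1.85 times what the spread between the shared aged vehicle libraries gives, so that the shared libraries and an effect of MLN4924 cannot be told apart. Length as the cause of the excess over that part cannot be told apart either: 72.3% of it was left after the length correction, but it was positive without aged vehicle 1 (0.0688, corrected 0.0889) and aged vehicle 3 (0.045, corrected 0.0697), against -0.356 (corrected -0.332) without aged vehicle 2. The length correction took Spearman's rho with length from 0.39 to -0.01 for age. It left 82.7% to 94.2% of the covariance with each library left out. The part that the shared aged vehicle libraries give was -0.0952 before and -0.0956 after the correction. A large share would thus be left even if length caused the rest. The test therefore could not decide on a length trend as the cause of the whole covariance. With the atrial score removed the correlation was -0.45, below the lowest simulated without an effect of MLN4924 (-0.29). That bound was too weak, since the range simulated without any effect was -0.47 to -0.40. The covariance was then -0.076, against -0.176 as measured. It was not below the lowest simulated without an effect of MLN4924 (-0.0886, mean -0.0712). Atrial tissue therefore cannot be told apart from an effect of MLN4924 here, which remains a hypothesis.

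Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In aged against young vehicle 2 splits gave as many genes at an unadjusted p under 0.05 as the real 3837 (highest other 4128) and 9 gave as many lists as the real 11 (highest other 21). The split of young vehicle 1, young vehicle 2 and aged vehicle 2 against the rest, which follows the atrial transcripts, gave 4128 and called 1275 genes, against 0 for the real split, which points to a structure of the samples. In MLN4924 against aged vehicle 1 split, the real one, gave 2342 genes (highest other 1988, with 18 genes called, for aged vehicle 1, aged vehicle 3 and aged MLN4924 1 against the rest) and 7 gave as many lists as the real 20 (highest other 29). In MLN4924 against young vehicle 3 gave as many genes as the real 946 (highest other 1486) and 1 as many lists as the real 25 (highest other 24).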
